A study of Mus musculus with 2 samples.

How the data were processed

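Prostate tissue of male ICR mice was measured by single-cell RNA sequencing with unique molecular identifiers (UMIs) on the BD Rhapsody platform, in 2 libraries, 1 labelled CON and 1 labelled BPH. Per the labels, tissue was dissociated with collagenases, red cells were lysed and cells were stained for viability. The deposited count tables hold raw UMI counts per gene and cell, 1 table per library. The labels name STAR and the genome build mm10, without a version or a stated role, and the counting step and annotation are not stated. A deposited normalized table holds natural log values, ln of 1 plus the count scaled to a fixed total per cell. This was checked on 50702 values, with a largest difference of 0.000415. That table lists 12392 CON and 11404 BPH cells with 214 to 6002 detected genes and at most 20.0% mitochondrial counts. It holds 0 of the 13 mitochondrial genes of the count tables. It was used only to define an alternative set of cells, since its values are not counts. Columns of a further library that matches no labelled sample, 17216 in the series count table and 13327 in the normalized table, were not used here.

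The lists of groups, comparisons, gene lists, markers, naming rules for genes and a first set of other settings were fixed before the data were examined. The CON count table held 16062 cells and 121411016 UMIs, and that of BPH 14748 cells and 115528776 UMIs. Cells with under 200 detected genes (1259 CON, 1148 BPH) or over 25% mitochondrial counts (3144 and 2834) were left out, 3151 and 2837 in all. Scrublet, run per library, marked 222 and 158 doublets, which were removed. This left 12689 CON and 11753 BPH cells, with medians of 2473 and 2555 genes and 6.64% and 7.10% mitochondrial counts. Cells of both libraries were clustered together in scanpy 1.11.5, with counts per 10000, log1p, 2000 variable genes chosen within libraries, 30 principal components and 15 neighbours. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 gave 46 clusters, with no batch integration. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9.

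Each cluster took the class of the best of 27 fixed marker lists. The score was the mean log2 CPM of the markers above the lower quartile over clusters, with 10 added to each CPM, and a class needed a score of 3 and 3 markers seen in at least 20% of the cluster's cells. Clusters in which markers of another class or lineage led, those led by nerve cell genes, and a shallow cluster with no own marker leading against all other clusters stayed unnamed. Against clusters of other classes, the leading genes of that shallow cluster did include the secretory luminal markers Tgm4 and Pbsn. The markers were fixed beforehand, but this scoring rule, its limits and its exceptions were adjusted over several rounds after the clusters had been seen. Classes are therefore named as resembling a cell type, and unnamed cells were 4.26% of CON and 3.79% of BPH. Shares have exact Clopper-Pearson 95% intervals.

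UMIs were summed per library, over all cells and within each class with at least 50 cells in each library, and divided by the total (CPM). Ratios are BPH over CON with an exact conditional 95% interval for a pair of Poisson counts, and CPM values have exact Poisson intervals. All intervals cover counting error only, and those of gene ratios and list medians leave out variation between cells. With 1 library per group no test was made and no p-value is given. Named genes are the 5 highest and 5 lowest ratios over whole libraries, the 10 highest and lowest in the 3 largest classes, and the 3 highest and lowest in other classes, of which the text prints a part. They had at least 50 UMIs (200 over whole libraries), 100 CPM in the higher library, a UMI in 20% of its class cells and 20% of the highest class CPM of that gene. Mitochondrial, cytosolic ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out of this ranking. Members of the fixed lists could also be named. Some genes that these rules pick are not reported here.

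For each of 32 fixed gene lists with at least 5 members of at least 20 UMIs in a class, the median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins. That percentile describes these libraries and is not a p-value. Intervals of medians come from 1000 Poisson redraws of the counts. A zero count enters a ratio as 3 counts but a redraw as 0.5, so a median that rests on a zero (adipocyte markers in macrophage-like cells) is given as a bound without an interval. A member counted as higher or lower at a ratio of 1.5 or its inverse with an interval that excludes 1. The text gives gene lists in the classes at which they are aimed. It also gives marker lists of cell types in classes at which they are not aimed, pairs that the plan for list medians did not name. Which pairs of either kind are shown was decided in part after values had been seen. The rule by which a list counts as turned around (outside the central 95% of random lists, with a change of sign) was set after a first output. Smooth muscle markers in fibroblast-like cells, interferon genes in dendritic cell-like cells and goblet cell markers over whole libraries were picked after their values were seen.

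The settings fixed beforehand covered the cell filters, doublets, Leiden resolution (0.5 and 2.0), clustering each library on its own, other scalings (median-of-ratios, and totals without the 20 top genes), the mean of per-cell CPM, cells thinned to 1000 UMIs (147 CON and 111 BPH cells were too shallow), subtraction of 5% free RNA, and UMI minimums of 100 or of 1 for list members. Settings added after the data were seen were the cells of the deposited normalized table, equal weights for the clusters of a class, naming the shallow cluster secretory luminal, and cell cycle lists without the 10 cells of each library with most of their UMIs. Equal weights used 11 of the 12 fibroblast clusters. The calls were tested on simulated data in 4 classes, where 2-fold higher genes were called in 100% of cases, 2-fold lower genes in 94% to 100%, and unchanged genes in 0.238% to 0.547%. Both simulated libraries were Poisson draws from the CON sums of the class, for genes with at least 50 UMIs in CON. They hold no variation between cells, animals or dissections, so these rates cover counting error only and are not error rates of the comparison.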

Results

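Single-cell RNA was measured in prostate tissue of male ICR mice, an outbred stock, in 2 libraries, 1 per group. The labels' design text describes removal of both testes at 5 weeks of age, 1 week of recovery and 3 weeks of daily injections. The library labelled BPH came from mice given testosterone propionate at 7.5 ml/kg, and the library labelled CON from a control group given 200 µl of soybean oil. The labels do not say whether the control mice also lost their testes, nor how many mice entered each library. Directions below are therefore between 2 libraries and not between an androgen-deprived and an androgen-given state. The series title speaks of intestinal goblet cells, while the sample labels name prostate tissue. After filters, 12689 CON cells with 112185264 UMIs and 11753 BPH cells with 107662672 UMIs remained, at medians of 7540 and 8087 UMIs per cell. With 1 library per group no test was possible. Ratios are BPH over CON, and the ranges in parentheses are exact 95% intervals that cover counting error only, not differences between animals or dissections. Those of gene ratios and list medians take UMIs as independent counts, so variation between the cells of a library is not covered either. Members counted as higher or lower rest on the same intervals.

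The first comparison asked how the cell makeup of the tissue differed between the libraries. Endothelial cells made up 3.18% (2.88 to 3.50) of the CON library and 5.96% (5.53 to 6.40) of the BPH library, a ratio of 1.88 (1.66 to 2.13). Immune cells made up 14.0% (13.4 to 14.6) and 18.4% (17.7 to 19.1), a ratio of 1.31 (1.23 to 1.40). Epithelial cells held nearly equal shares, 18.6% (18.0 to 19.3) and 18.5% (17.8 to 19.2). Mesenchymal cells, which were mostly fibroblast-like, held 58.9% (58.1 to 59.8) in CON and 52.0% (51.1 to 52.9) in BPH. The order of the mesenchymal shares turned around, to 36.4% and 40.3%, when each library was clustered on its own. Epithelial shares rose only to 21.8% and 21.1% in that setting, and endothelial and immune shares were not among those that moved. The reversal thus came with many cells left outside these lineages. Cells left unnamed were 4.26% of CON and 3.79% of BPH.

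Within these lineages, vascular endothelial-like cells were 2.62% (2.35 to 2.92) of CON and 5.40% (5.00 to 5.83) of BPH, a ratio of 2.06 (1.80 to 2.36). B cell-like cells had a ratio of 3.15 (2.43 to 4.14), monocyte-like cells 2.74 (2.02 to 3.75), T cell-like cells 1.68 (1.37 to 2.07) and macrophage-like cells 1.19 (1.09 to 1.30). The monocyte-like ratio was 5.78 with each library clustered on its own, a setting in which no CON cells were named dendritic cell-like. Mast cell-like cells went the other way, 0.772% (0.627 to 0.940) in CON and 0.425% (0.316 to 0.560) in BPH. Secretory luminal-like cells, the glandular cells that make prostatic fluid, were 10.4% (9.88 to 11.0) of CON and 7.46% (6.99 to 7.95) of BPH. Their ratio was 0.717 (0.657 to 0.781), and it was 0.468 when cells above 10% mitochondrial counts were left out. Of the epithelial cells alone they were 55.8% (53.8 to 57.8) in CON and 40.4% (38.3 to 42.5) in BPH. The nearly equal epithelial shares thus hold a different mix of classes. A cluster of shallow cells whose best markers were also secretory luminal stayed unnamed and held 2.88% of CON and 2.43% of BPH. Proximal luminal-like cells, from the duct region next to the urethra, held 3.24% and 2.88%, and their ratio of 0.891 (0.769 to 1.03) became 1.42 below 10% mitochondrial counts. Cells that carried general epithelial markers only had a ratio of 2.48 (2.10 to 2.95), seminal vesicle-like cells 1.54 (1.28 to 1.85) and smooth muscle-like cells 1.68 (1.39 to 2.03). The first of these classes is so named because no more specific epithelial list reached the limits. It joins cluster 20, led by Akr1b7, Crisp1 and Serpina1f, and cluster 27, led by 2310057J18Rik, Prol1 and Smr2. Whether its cells belong to the prostate or to other tissue in the dissection was not tested.

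**Figure D1:**
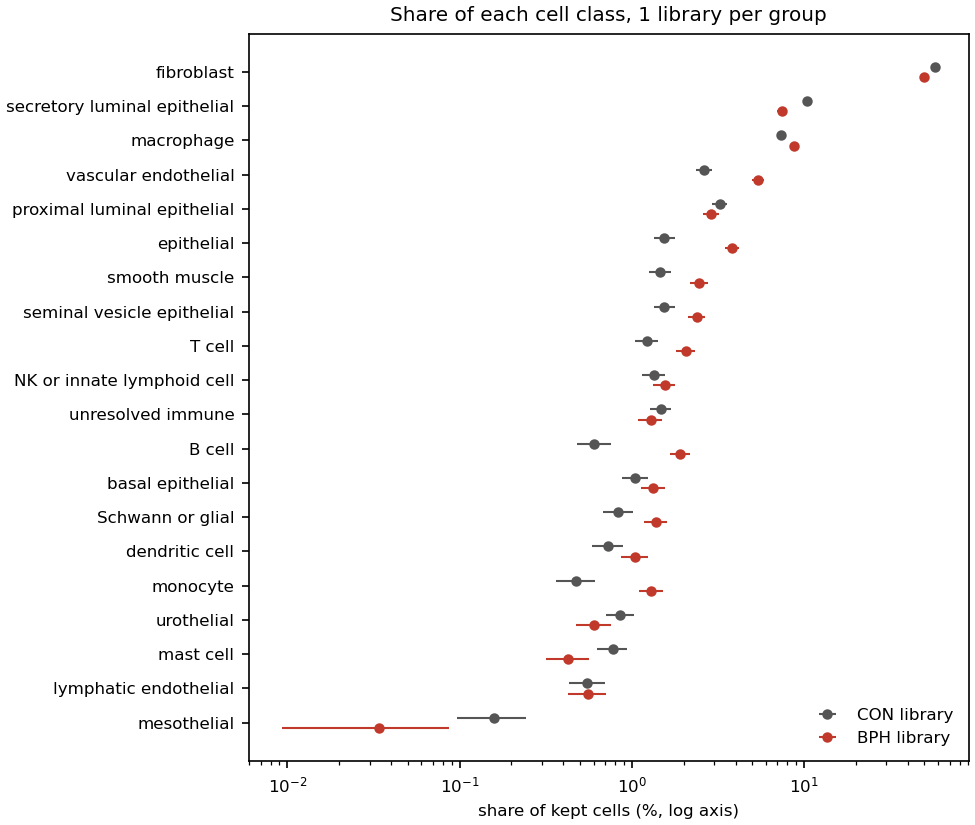
Share of kept cells per cell class (percent) in the CON and BPH libraries, with exact 95% binomial intervals as error bars. Fibroblast-like cells are the largest class in both libraries, at 57.5% of CON and 49.5% of BPH, and vascular endothelial-like cells stand at 2.62% and 5.40%.

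Highest and lowest ratios of single genes are given here and below among ranked genes only, those with at least 100 CPM in the higher library and, within classes, a UMI in 20% of its cells, along with the other limits of the ranking rule. Members of fixed lists that are expressed below those limits had larger ratios in several classes. Over the whole libraries, the 5 ranked genes with the highest ratios were Serpina1f (3.01, 2.93 to 3.10), Coro2a (2.89), Akr1b7 (2.77), Crisp1 (2.64) and Mup4 (2.51). Akr1b7, an aldose reductase-like enzyme, stood at 348 CPM (345 to 352) in CON and 965 CPM (959 to 971) in BPH. Serpina1f, Akr1b7, Crisp1 and Mup4 lead the clusters that carry general epithelial markers only, so their whole-library values move with the share of those cells. Within that class their ratios were 1.27, 1.15, 1.16 and 1.08. Of the 13663 UMIs of Coro2a in BPH, 8746 lay in seminal vesicle-like cells. The lowest whole-library ratios among ranked genes belonged to Scgb2b27 (0.167, 0.160 to 0.175), Agr2 (0.433), Spinkl (0.460), Spink1 (0.460) and Tgm4 (0.465). Tgm4, the prostate transglutaminase of the copulatory plug, had 2125 CPM (2116 to 2133) in CON and 988 CPM (982 to 994) in BPH. In secretory luminal-like cells alone the ratios of Spink1 and Tgm4 were 0.771 and 0.770, that of Agr2 was 0.698 and that of Scgb2b27 was 0.291. Tgm4 and Agr2 are among the leading genes of cluster 14, which held 377 CON and 103 BPH cells. Spink1 and Scgb2b27 lead cluster 35, with 131 and 66, so the mix of clusters can enter these ratios. Tgm4 had a UMI in 51.2% of all CON cells and 29.0% of BPH cells, while 10.4% and 7.46% were secretory luminal-like. Its whole-library ratio thus also counts UMIs in other classes, where free RNA was not told apart.

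Because the series title names goblet cells, markers of intestinal goblet cells were read over the whole libraries. Of 6 measured markers 4 were lower in BPH and 0 higher, with a median log2 ratio of -0.95 (-1.09 to -0.80). The most abundant was Agr2, which prostate epithelium also expresses, while Muc2, the gel mucin of goblet cells, had 33 UMIs in CON and 28 in BPH.

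In secretory luminal-like cells the question was whether androgen-regulated genes differed between the libraries. Of the 24 measured members of the list of genes induced by androgen in prostate, 5 were at least 1.5-fold higher in BPH and 0 were lower by that margin. The 5 were Msmb (2.16), which encodes beta-microseminoprotein, Tsc22d3 (1.94), Fkbp5 (1.72), a co-chaperone of steroid receptors, Homer2 (1.61) and Zbtb16 (1.53). With equal cluster weights the log2 ratio went from 1.11 to 0.17 for Msmb and from 0.79 to 0.30 for Fkbp5, both short of 1.5-fold, so the count of 5 rests partly on the mix of clusters. The list's median log2 ratio was -0.08 (-0.12 to 0.02), at percentile 33.8 of random lists matched on expression. Probasin (Pbsn) had a ratio of 0.951. Of the 11 genes of the list raised by castration, 1 was higher (Clu, 1.68) and 3 were lower (Psca, 0.340, Wfdc2, 0.279, and Igfbp3, 0.244). Its median was -0.19 (-0.31 to -0.09), at percentile 10.9 and so within the range of random lists. Psca and Wfdc2 are leading genes of cluster 17 of the proximal luminal-like cells, and proximal luminal markers were lower in the secretory luminal-like cells too, with a median of -0.45 (-0.85 to -0.11) and 3 of 8 lower.

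Among the ranked genes of secretory luminal-like cells, Mgll, the monoacylglycerol lipase, had the highest ratio (2.35, 2.17 to 2.54), followed by Msmb, Tent5a (2.01), the defensin Defb50 (2.01), Wfdc3 (1.92), Defb1 (1.90), Pcp4 (1.86), Fkbp5, Itln1 (1.69) and Snhg18 (1.69). Msmb, Defb50, Wfdc3, Defb1 and Itln1 are leading genes of cluster 18, which held 184 of the 1321 CON cells and 216 of the 877 BPH cells of the class. Defb50 stood at 9606 CPM (9560 to 9653) in CON and 19282 CPM (19195 to 19370) in BPH. The lowest ratios among ranked genes belonged to Sel1l (0.580, 0.542 to 0.620), a part of the machinery that removes misfolded proteins, Spcs3 (0.612), a signal peptidase subunit, and the chaperone Hsp90b1 (0.613). Fut9, Mcfd2, Slc7a1, Pdia4, Creld2, Pgm2l1 and Hspa5 followed, between 0.618 and 0.646. Hspa5, the main chaperone of the endoplasmic reticulum, had 5213 CPM (5179 to 5247) in CON and 3366 CPM (3330 to 3403) in BPH. The list of unfolded protein response and secretion genes had a median log2 ratio of -0.39 (-0.43 to -0.34), with 5 of 17 members lower, 0 higher and a percentile of 0. Housekeeping genes had a median of -0.16 in these cells, which became 0.050 with equal cluster weights, and mitochondrially encoded genes had 0.32. When every cluster of the class had the same weight, the log2 ratios moved from 1.01 to 0.19 for Defb50, from 0.94 to 0.13 for Wfdc3, from 0.92 to 0.19 for Defb1, from 0.90 to 0.07 for Pcp4, from 1.23 to 0.46 for Mgll and from 0.76 to -0.07 for Itln1. On the lower side that setting moved them from -0.65 to -0.12 for Pgm2l1, from -0.69 to -0.27 for Fut9, from -0.67 to -0.22 for Slc7a1 and from -0.63 to -0.35 for Hspa5, and the median of the unfolded protein response list to -0.17. Slc7a1 was at -1.30 in cells thinned to 1000 UMIs.

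Cell cycle genes were lower in secretory luminal-like cells of the BPH library, and 10 CON cells held much of their UMIs. Of 15 genes of G2 and M phase, 13 were lower and 0 higher, with a median log2 ratio of -1.89 (-2.12 to -1.35). Top2a, the topoisomerase of dividing cells, had 365 UMIs in CON and 100 in BPH, and Mki67 had 145 and 39. Of the list's 3614 UMIs in CON, 51.0% came from 10 of the 1321 cells, against 17.7% of 1074 UMIs from 10 of the 877 BPH cells. Without those 10 cells per library the median was -0.10 (-0.44 to 0.18), but cells picked on the same genes would lower a difference of any origin. By cluster, the ratio of the list's UMIs was 0.165 (0.134 to 0.201) in cluster 35 and 0.610 (0.538 to 0.689) in cluster 14, but 0.931 (0.752 to 1.15) in cluster 18, 1.10 (0.946 to 1.28) in cluster 7 and 1.48 (1.15 to 1.91) in cluster 29. Cells with at least 3 of the genes were 7.72% (6.34 to 9.29) of the class in CON and 4.22% (2.99 to 5.77) in BPH. These shares also depend on depth per cell, and the class medians were 9045 UMIs in CON and 7753 in BPH. Cluster 14, at medians of 24586 and 25584 UMIs, held 377 of the CON cells and 103 of the BPH cells. In cells thinned to 1000 UMIs only 3 members could be measured, with a median of 0.14 (-0.47 to 0.51). S phase genes had a median of -0.57 (-0.78 to -0.36), with 5 of 15 lower, and -0.51 (-0.66 to -0.23) without the 10 cells with most of their UMIs. In fibroblast-like cells 9 of 15 G2 and M genes were lower, with a median of -0.66 (-0.85 to -0.50). That median was -0.26 in thinned cells and -0.34 with equal cluster weights, and cells with at least 3 of the genes held similar shares, 1.15% (84 of 7293) in CON and 1.06% (62 of 5822) in BPH. In macrophage-like cells 7 of 14 were higher, with a median of 0.64 (0.36 to 0.85) that was 0.19 with equal cluster weights.

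Among the other epithelial classes, proximal luminal-like cells had the highest ratios among ranked genes at Krt6a, a keratin of stressed epithelium (3.34, 2.87 to 3.91), Ceacam2 (2.98) and Igfbp2 (2.49), and the lowest at Cxcl17 (0.387), Scara3 (0.396) and Pigr (0.405), the transporter of secretory antibodies. Cluster 17 held most of this class in CON (65.7%) and cluster 24 most of it in BPH (57.5%). With equal weights for those clusters the log2 ratio of Igfbp2 went from 1.32 to 0.66. In cells thinned to 1000 UMIs it was 2.08, and that of Scara3 went from -1.34 to -2.01. The list raised by castration had a median log2 ratio of 0.12 (0.07 to 0.21) there, with 1 of 11 members higher (Cd74). Androgen-induced genes had a median of 0.13 (-0.05 to 0.19), with 4 of 24 higher and 5 lower. Both lists lay within the range of random lists, at percentiles 91.0 and 97.1. In the same cells immediate early genes had a median of -0.40 (-0.42 to -0.37), with 3 of 20 lower, mitochondrially encoded genes -0.21 (-0.22 to -0.20) and fibroblast markers -0.80 (-0.91 to -0.67), with 8 of 10 lower, all 3 below the central 95% of random lists. In basal-like cells, Clu had the lowest ratio among ranked genes (0.266, 0.229 to 0.308) and the list raised by castration a median of -0.39 (-0.60 to -0.27), with 2 of 9 lower. In the class with general epithelial markers only, Aqp2, a water channel, had the highest ratio among ranked genes (13.6, 11.9 to 15.5), and androgen-induced genes had a median of -0.25 (-0.53 to -0.11), with 3 of 24 higher and 9 lower. Secretory luminal markers had a median of -1.63 (-2.18 to -1.40) in that class, with 7 of 10 lower and 2 higher, and immediate early genes -0.49 (-0.51 to -0.40), with 5 of 20 lower, both below all random lists. Aqp2 there moved from a log2 ratio of 3.76 to 4.78 among the cells of the deposited normalized table. In seminal vesicle-like cells 6 of 9 seminal vesicle markers were lower in BPH and 0 higher, with a median of -1.34 (-1.43 to -1.26), and the lowest ranked ratios were 0.185 for Svs6, 0.220 for Spinkl and 0.231 for Svs1. Their median depth was 7772 UMIs in CON and 18943 in BPH, and with every cell weighted alike the log2 ratio was -0.94 in place of -2.11 for Svs1, -1.66 in place of -2.44 for Svs6 and -1.38 in place of -2.19 for Spinkl. Urothelial-like cells differed too much in depth, at medians of 13997 and 1869 UMIs, for their gene ratios to be read.

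In fibroblast-like cells, the largest class, the ratios of ranked genes lay between 0.606 and 2.04. Cyp1b1, a cytochrome P450 that metabolises steroids and aromatic compounds, had the highest of them, from 58.0 CPM (56.2 to 59.9) in CON to 118 CPM (115 to 121) in BPH, or 2.04-fold (1.96 to 2.12). Dkk3 (1.84), the GDNF receptor gene Gfra1 (1.67), Chodl (1.59), the mesenchymal transcription factor Foxf1 (1.56), Plxdc2 (1.54), the retinoic acid enzyme gene Aldh1a2 (1.52), Tgfbi, C4b (1.44) and Nt5e (1.43) followed. Dkk3 is a leading gene of cluster 38, which held 20 CON and 116 BPH cells, and its log2 ratio went from 0.88 to 0.12 with equal cluster weights. The same weights moved Tgfbi from 0.58 to 0.06, Chodl from 0.67 to 0.21, Aldh1a2 from 0.60 to 0.33, Foxf1 from 0.64 to 0.36 and, on the lower side, Igfbp5 from -0.66 to -0.22, while Cyp1b1 was at 1.18. The lowest ratios of ranked genes were those of Angpt4 (0.606, 0.592 to 0.621), Pianp (0.619) and Igfbp5 (0.633), a binding protein of insulin-like growth factors. Sgk1, Rnd3, Ier5, Cdkn1a, Ackr3, Cyr61 and Nfil3 followed, between 0.662 and 0.693.

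Extracellular matrix genes in fibroblast-like cells had a median log2 ratio of 0.12 (0.10 to 0.12), above all random lists, but only Tnc among 30 members passed 1.5-fold. Tnc, which encodes tenascin C, had 585 UMIs in CON and 2306 in BPH, a ratio of 4.38 with an interval up to 4.81, and is also a leading gene of cluster 38. The collagen gene Col1a1 had a ratio of 1.32 and Timp3, a protease inhibitor gene, 1.38. Of 29 growth factor and morphogen genes, 3 were higher (Pdgfb, 3.91, Grem1, 1.78, and Igfbp2) and 4 lower (Fgf18, 0.367, Igfbp3, 0.441, Egf, 0.560, and Igfbp5), with a median of -0.06 (-0.08 to -0.03). Egf rests on 129 and 65 UMIs, Grem1 on 50 and 80 and Pdgfb on 31 and 109, the last at 0.493 and 1.93 CPM. Markers of several other types were lower in the same cells, all below all random lists. Medians were -0.87 (-1.17 to -0.65) for secretory luminal (7 of 11 lower) and -1.12 (-1.20 to -1.04) for seminal vesicle markers (6 of 9 lower, 1 higher). Urothelial markers were at -1.26 (-1.49 to -0.58, 4 of 5 lower) and mast cell markers at -1.13 (-1.40 to -0.85, 4 of 5 lower, 1 higher). These values are not read as changes in fibroblast-like cells. Free RNA, caught cells of those types and expression by the class itself were not told apart, here or for other types' markers in other classes. TGF-beta response and myofibroblast genes had a median of 0.19 (0.16 to 0.23), with Acta2 (2.07) and Tagln (1.57) higher, and a median of -0.0029 with equal cluster weights. Smooth muscle markers, some of them shared with that list, had a median of 0.44 (0.26 to 0.52) in the same cells, with 4 of 8 higher. Of 14 genes of steroid receptors and enzymes, only Srd5a2, which makes dihydrotestosterone, was lower by the margin (0.376, 0.325 to 0.435), and the median was -0.0012. Of 29 cytokine and chemokine genes 1 was higher and 4 were lower, with a median of -0.13 (-0.22 to -0.04) that became 0.0032 with equal cluster weights.

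In macrophage-like cells the medians of antigen presentation and classical activation genes were higher in the BPH library by small folds, with few members past 1.5-fold. MHC class II presentation genes had a median log2 ratio of 0.45 (0.44 to 0.50), above all random lists, with 1 of 8 at least 1.5-fold higher (Ciita, 1.90). Cd74 had a ratio of 1.41 and H2-Ab1 1.47, while H2-Eb1 was at 0.841. Genes of classical activation had a median of 0.32 (0.29 to 0.47), with 2 of 9 higher, Cxcl9 (5.10, 4.15 to 6.32) and Il12b (1.54), and Il1b at 1.48. With equal cluster weights the 2 medians were 0.22 and 0.19. Dendritic cell markers were also higher in these cells, with a median of 0.66 (0.50 to 0.76), above all random lists, and 3 of 6 higher, and an admixture of dendritic cells was not tested. Tissue-resident genes had a median of -0.27 (-0.31 to -0.25), with 1 of 12 lower by the margin (Lyve1), and genes of alternative activation -0.21 (-0.28 to -0.12), with 0 of 7 beyond it. The resident and alternative medians became 0.02 and 0.03 with equal cluster weights, and cluster 5 held 62.4% of the class in CON and 45.2% in BPH. NF-kB targets had a median of 0.18 (0.15 to 0.24), oxidative stress defence genes -0.27 (-0.31 to -0.20), with 3 of 19 lower by the margin, and complement genes -0.29 (-0.37 to -0.14), with 3 of 13 lower. Markers of other types differed in the same cells: all 5 adipocyte markers were lower, with a median of -4.90 that is a bound because its middle member has 0 UMIs in BPH. Fibroblast markers had a median of -1.01 (-1.17 to -0.87), proximal luminal markers -0.997 (-1.29 to -0.69), with 5 of 8 lower, and vascular endothelial markers 0.65 (0.43 to 0.89), with 4 of 8 higher. The complement members Cfd, C1s1 and Serping1 that were lower are also fibroblast or adipocyte products. Cytokine genes had a median of -0.05 (-0.11 to -0.01) and lipid-associated macrophage genes -0.07 (-0.09 to -0.03), within the range of random lists. The lipid-associated median became 0.13 with every cell weighted alike, and the cytokine median 0.032 with equal cluster weights.

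The highest ratio of a ranked gene in macrophage-like cells was that of Gdf15, a stress-induced cytokine of the TGF-beta family, from 236 CPM (224 to 247) in CON to 763 CPM (744 to 783) in BPH, or 3.24-fold (3.07 to 3.42). Slamf7 (1.92), Cd72 (1.87), the fractalkine receptor gene Cx3cr1 (1.83), Gpr132 (1.81), Got1, Itgb5, Runx3, Arl5c and the growth factor gene Areg (1.65) followed. With equal cluster weights the log2 ratio went from 0.75 to 0.17 for Runx3, from 0.73 to 0.23 for Arl5c, from 0.77 to 0.28 for Itgb5, from 0.90 to 0.33 for Cd72 and from 0.87 to 0.35 for Cx3cr1, while that of Gdf15 was 1.75. Among the lowest were Fcna, a ficolin gene (0.510, 0.491 to 0.530), Rgl1 (0.562), the chemokine receptor gene Ccr1 (0.585) and Lyve1, a hyaluronan receptor gene (0.604). Tslp, Gclc, Ccl6, Hmox1 and Mt2 followed, between 0.649 and 0.671. Hmox1, the haem oxygenase that answers oxidative stress, had 4561 CPM (4511 to 4612) in CON and 3057 CPM (3018 to 3096) in BPH.

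**Figure D2:**
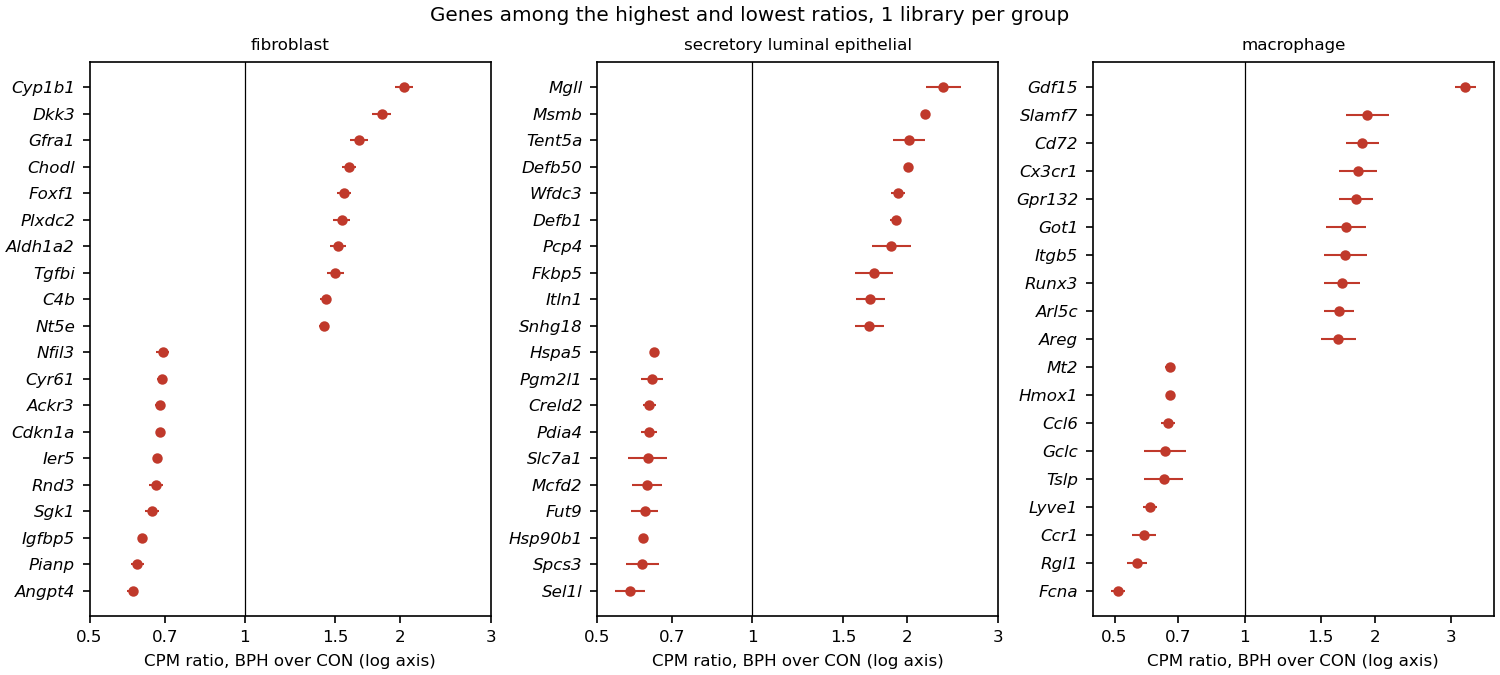
BPH over CON ratio (log axis) of genes among the 10 highest and 10 lowest of the ranked genes in fibroblast-like, secretory luminal-like and macrophage-like cells, with exact 95% counting intervals as bars. Ratios run from 0.510 for Fcna to 3.24 for Gdf15, both in macrophage-like cells.

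In vascular endothelial-like cells, 5 of 12 angiogenic genes were higher in BPH and 0 lower. They were Apln (2.61, 1.14 to 6.96, from 7 and 34 UMIs), Pgf (2.39), Esm1 (1.69), Aplnr (1.69) and Plvap (1.52), while the receptor genes Kdr and Flt1 were at 1.05 and 1.10. The median was 0.16 (0.09 to 0.44), at percentile 94.0 and so within the range of random lists. Markers of other types were lower in the same cells, with medians of -1.04 for pericytes (5 of 6 lower), -1.04 for secretory luminal cells (4 of 7 lower) and -0.46 for fibroblasts (4 of 10 lower), all 3 below all random lists. Of 12 G2 and M genes 6 were higher, with a median of 1.08 (0.59 to 1.53), but 10 cells held 47.7% of the 866 UMIs in BPH, and the median was -0.15 (-0.57 to 0.22) without the 10 cells of each library, which were picked on the same genes, and 1.67 with equal cluster weights. S phase genes had a median of only 0.023 in these cells, with alternatives from -0.75 to 0.032. Prcp (2.01), Ccdc3 (1.88) and Myof (1.81) had the highest ratios among ranked genes. The interferon-induced gene Ifit1 (from 109 to 54.6 CPM), the semaphorin gene Sema3g (0.525) and Cldn5, the endothelial tight junction gene (0.555, 0.520 to 0.592), had the lowest. Plvap is a leading gene of cluster 10, which held 58.0% of the class in CON and 68.5% in BPH, and Cldn5 of cluster 22. Across the alternative settings the log2 ratio lay between -0.89 and -0.55 for Cldn5 (main -0.85) and between -1.06 and -0.51 for Sema3g (main -0.93). For Myof it lay between 0.39 and 0.93 (main 0.86). Immediate early genes had a median of -0.28 (-0.30 to -0.23) in vascular endothelial-like cells, with 0 of 20 beyond 1.5-fold.

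**Figure D3:**
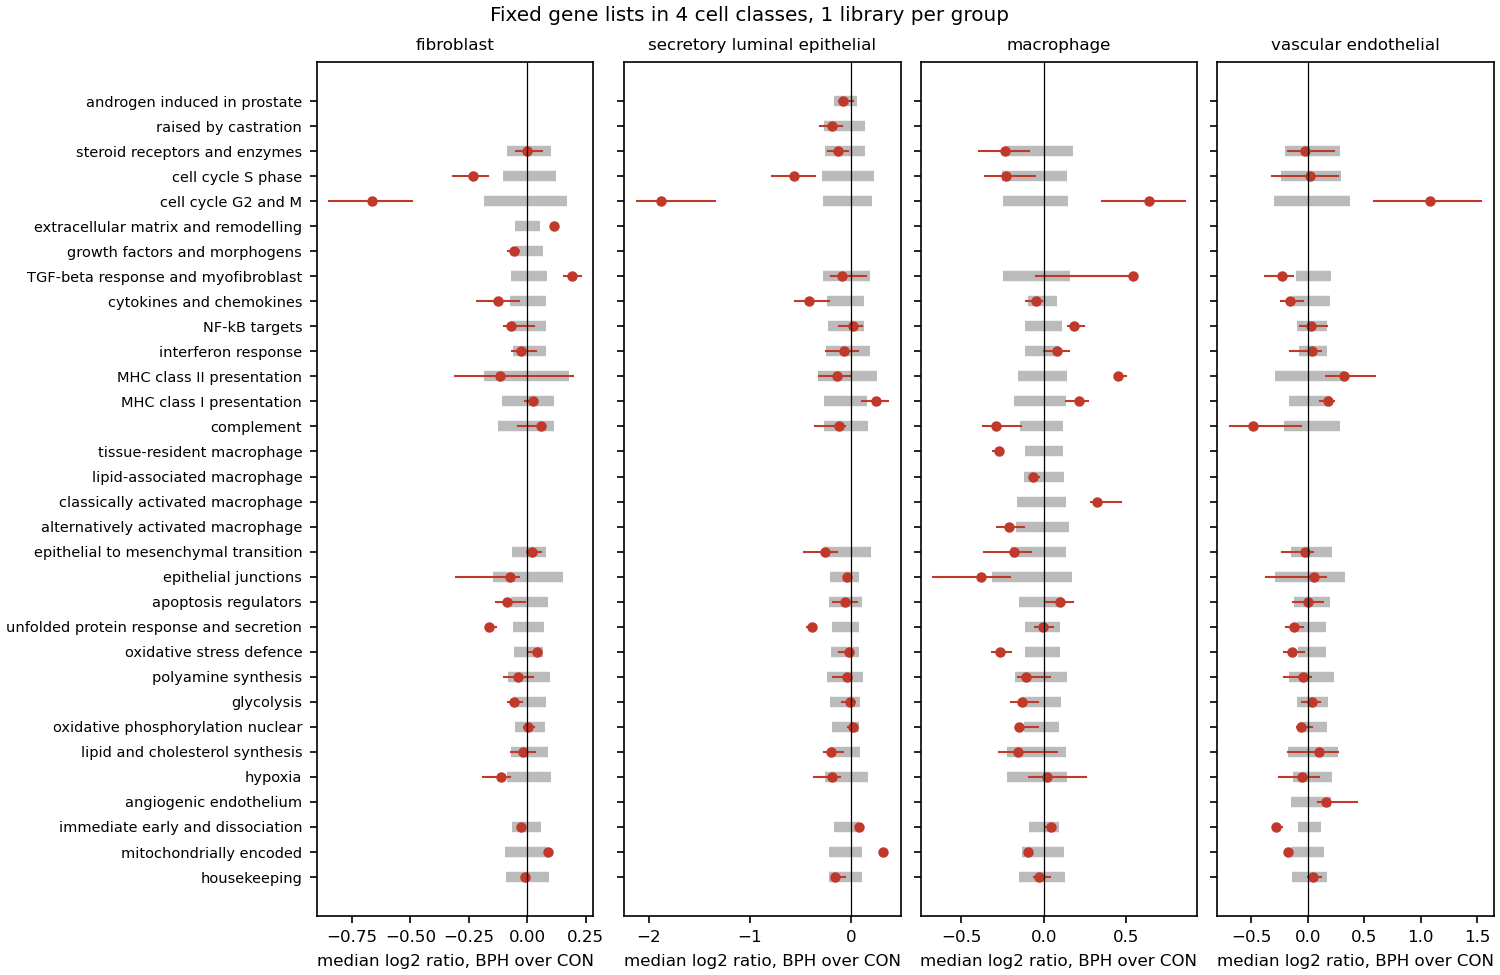
Median log2 BPH over CON ratio of fixed gene lists (points) in 4 cell classes, with 95% counting intervals (red bars) and the central 95% of random lists matched on expression (grey bars). MHC class II presentation stands at 0.45 in macrophage-like cells and the unfolded protein response and secretion list at -0.39 in secretory luminal-like cells.

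The smaller immune and stromal classes had few cells, 50 to 289 per library, and correspondingly wide intervals. Dendritic cell-like cells had 10 of 14 interferon response genes higher in BPH, with a median of 1.73 (0.90 to 1.96). Isg15 had 5 and 55 UMIs and Irf7 12 and 65, and the median was 0.72 among the cells of the deposited normalized table and 0.54 for members with at least 100 UMIs. H2-Eb1 was among the lowest genes of these cells, at 0.361 (0.344 to 0.379). In T cell-like cells Tigit (3.27, 1.88 to 6.07), an inhibitory receptor gene, and Tbc1d4 (3.13) were among the genes with the highest ratios. In the same cells fibroblast markers had a median of -2.16 (-2.34 to -1.64), with 8 of 9 lower, immediate early genes -0.66 (-0.75 to -0.50), with 10 of 20 lower, and NK cell markers -0.66 (-0.78 to -0.46), with 4 of 6 lower. Fibroblast markers were also lower in monocyte-like cells (-1.71, 9 of 10 lower), and higher in mast cell-like cells (0.92, 7 of 8 higher). Tigit was also highest in NK or innate lymphoid-like cells (2.09, 1.39 to 3.20). Aass, which starts lysine breakdown, had the lowest ratio of a ranked gene in both, 0.100 (0.0578 to 0.165) and 0.171 (0.110 to 0.257), and in the class with general epithelial markers only, 0.331 (0.292 to 0.375). Its log2 ratio in NK or innate lymphoid-like cells moved from -2.55 to -3.66 in thinned cells. Among ranked genes, monocyte-like cells had the lowest ratio at Fabp5 (0.125, 0.0825 to 0.185), and mast cell-like cells the highest at Gdf15 (6.77, 3.84 to 12.6). The log2 ratio of Fabp5 was -1.59 in thinned cells in place of -3.00. B cell-like and lymphatic-like cells had their lowest ranked ratios at collagen genes, 0.186 for Col3a1 and 0.136 for Col1a2, which are fibroblast products. Weighting every cell alike moved these log2 ratios from -2.43 to -1.31 and from -2.88 to -1.61, thinning to -1.40 and -1.42, and subtracting 5% free RNA to -4.57 and -6.77. In smooth muscle-like cells Ctgf (2.25) and Abcc9 (2.15) were among the genes with the highest ratios, with cluster 31 holding most of the class in CON and cluster 30 in BPH. Vascular endothelial markers were higher in these cells as well, with a median of 1.83 (1.02 to 2.60) and 4 of 5 higher, and so were fibroblast markers, at 0.56 (0.49 to 0.64) with 5 of 10 higher.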

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

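Of the tests below, those on the 10 cells, on S phase genes and all 3 on the vascular share were chosen only after the result was seen, the readings of the 10-cell, depth and S phase tests and the scope of the first marker test were revised after their values were seen, and the test on epithelial markers was added last, with its bounds written before its value.

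G2 and M phase genes were lower in secretory luminal-like cells of the BPH library, with a median log2 ratio of -1.89 (-2.12 to -1.35). The values argue against a different mix of clusters as the whole cause, since the median was -1.02 (-1.66 to -0.71) with equal cluster weights. In CON cells with at least 3 G2 and M genes, fibroblast, macrophage and endothelial markers were 0.820 (0.782 to 0.859) times those of the other cells. Basal and proximal luminal markers were at 0.904 (0.764 to 1.06) and 1.30 (1.25 to 1.35), and secretory luminal markers at 0.720 (0.716 to 0.723). These averages argue against cells of those other types making up most of the 102 cells. They cannot tell the type of the 10 CON cells that held 51.0% of the list's UMIs, so caught cells of another type stay open as a cause. A few cells as the cause cannot be told apart: the median was -0.10 (-0.44 to 0.18) without the 10 richest cells of each library, but these were picked on the same genes, which would lower a real difference too. Thinning cannot decide on depth per cell, because the median was then 0.14 (-0.47 to 0.51) on 3 members. Only 9 CON cells and 3 BPH cells, 0.345% (0.0713 to 1.01) of the BPH class, had at least 3 of the genes. The prediction written beforehand read overlapping intervals as depth being the cause, which so few cells cannot show. Depth by cluster was compared after these results were seen. CON and BPH medians were 16483 and 15308.5 UMIs in cluster 35 (list ratio 0.165) and 24586 and 25584 in cluster 14 (0.610). These values argue against depth as the cause in those clusters, and the list was not lower beyond its interval in the other clusters of the class. Fewer cycling luminal cells in the BPH library also stays open, with an S phase median of -0.57 (-0.78 to -0.36). At the cells' own depth 7.72% (6.34 to 9.29) of CON and 4.22% (2.99 to 5.77) of BPH cells had at least 3 of the G2 and M genes. Those shares were not matched for depth: the class medians were 9045 UMIs in CON and 7753 in BPH, and the deep cluster 14 held 377 CON and 103 BPH cells. The groups also hold 1 library each.

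Aass was lower in T cell-like (0.100) and NK or innate lymphoid-like cells (0.171) of the BPH library. Free RNA is excluded as the cause, since Aass stood at 222 CPM in T cell-like cells of CON against 23.8 CPM over that library. A difference in genotype between outbred animals stays possible, as 88.9% of classes with at least 20 Aass UMIs (8 of 9) had a ratio below 1 with its interval. That count includes the T cell-like and NK or innate lymphoid-like cells that raised the question, and all classes come from the same 2 libraries. The lower ratios ran from 0.100 in T cell-like to 0.678 in secretory luminal-like cells, so the count is weak support. Fibroblast-like cells were the exception at 1.21 (0.861 to 1.69), near 1 CPM. An effect of the treatment on Aass would give the same pattern and was not tested.

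Vascular endothelial-like cells had a higher share in the BPH library, by 2.06 (1.80 to 2.36). A lower yield of fibroblasts is excluded as the whole cause, since among all other cells the ratio was 1.73 (1.52 to 1.99), and so is a looser filter on damaged cells, since the ratio was 2.60 (2.17 to 3.13) at no more than 10% mitochondrial counts. Growth of vessels could contribute, with a G2 and M median of 1.08 (0.59 to 1.53), but 10 cells held 47.7% of those UMIs in BPH. S phase genes showed no such rise, with a median of 0.023, and -0.19 (-0.41 to 0.094) without the 10 cells with most of their UMIs. Cells with at least 3 of the G2 and M genes were 3.46% (2.18 to 5.20, 22 of 635) in BPH and 1.80% (0.664 to 3.88, 6 of 333) in CON, with overlapping intervals. After thinning they were 4 and 1 cells, so growth of vessels stays open. Differences in dissection between the libraries were not tested and are confounded with the groups.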

How the results depend on the processing

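The alternatives on the cells of the deposited normalized table, on equal cluster weights, on the shallow cluster and without the 10 richest cells were chosen only after the data were seen. No paired analysis was possible because each group had 1 library. Cells kept ranged from 9956 to 14581 in CON and from 8878 to 13442 in BPH. Among alternatives, 291 shares lay within their counting interval and 93 moved; for list medians 969 stayed, 147 moved and 14 turned around; for named genes 999 stayed, 270 moved and 1 turned around. The endothelial ratio stayed between 1.85 and 2.18, and the immune ratio between 1.30 and 1.34. Among the medians that kept their sign throughout were those of fibroblast matrix genes (0.073 to 0.15), MHC class II genes in macrophages (0.22 to 0.48) and classical activation genes (0.19 to 0.38). So did those of angiogenic genes in vascular cells (0.11 to 0.35), and of S phase (-0.69 to -0.41) and unfolded protein response genes (-0.45 to -0.17) in secretory luminal-like cells. The -0.17, from equal cluster weights, lay within the random range of the main setting (-0.19 to 0.085). Thinned cells left under 5 members for the cell cycle lists of secretory luminal-like cells, too few for the comparison; the 3 G2 and M members left had a median of 0.14 (-0.47 to 0.51). Where a value moved, the cause was not tested, except that fewer cells or other weights are what each setting sets.

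At no more than 10% mitochondrial counts the CON and BPH shares were 12.2% and 12.2% epithelial, 68.3% and 60.8% mesenchymal, 2.38% and 5.18% endothelial, and 14.7% and 19.7% immune. Epithelial shares were 21.5% and 20.9% at Leiden resolution 0.5 and the same with the shallow cluster named secretory luminal. Clustering each library on its own gave 21.8% and 21.1% epithelial and 36.4% and 40.3% mesenchymal. The cells of the normalized table gave 17.3% and 17.0% epithelial and 60.8% and 53.5% mesenchymal, with medians of -0.95 for secretory luminal G2 and M genes and 0.047 for lipid-associated macrophage genes.

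In thinned cells, fibroblast medians were -0.26 for G2 and M, 0.13 for matrix, -0.087 for growth factors and 0.0071 for NF-kB targets. Macrophage medians were -0.0064 for cytokines, -0.33 for resident, 0.042 for lipid-associated and -0.34 for alternative activation genes. Immediate early genes in secretory luminal-like cells were at -0.065 (0.080 in the main setting). Genes raised by castration were at -0.045 in cells with general epithelial markers (main 0.24) and 0.23 in seminal vesicle-like cells (main -0.22).

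With equal cluster weights, fibroblast medians were -0.34 for G2 and M, 0.073 for matrix, -0.088 for growth factors, -0.0029 for TGF-beta response, 0.0032 for cytokines and 0.039 for apoptosis regulators (main -0.086). Macrophage medians were 0.032 for cytokines, 0.019 for resident, -0.11 for lipid-associated, 0.19 for classical and 0.026 for alternative activation genes. Secretory luminal G2 and M genes were at -1.02, castration genes in proximal luminal-like cells at 0.071 and Itln1 in secretory luminal-like cells at -0.075.

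With the mean of per-cell CPM, medians were 0.15 for matrix and -0.035 for growth factors in fibroblasts, -0.13 for androgen-induced, -0.88 for G2 and M and -0.058 for immediate early genes in secretory luminal-like cells, -0.35 for resident and 0.13 for lipid-associated macrophage genes, and -0.0087 for MHC class II genes in vascular cells (main 0.32). Median-of-ratios scaling gave -0.24 for resident macrophage genes, and totals without the top genes 0.12 for fibroblast matrix genes. Members with at least 100 UMIs gave -0.048 for castration genes in cells with general epithelial markers. Subtracting 5% free RNA gave -0.18 for TGF-beta response genes in macrophages (main 0.54). Without the 10 richest cells, G2 and M medians were -0.45 in fibroblasts, -0.10 in secretory luminal-like and -0.15 in vascular cells.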
